A study of Mus musculus with 4 samples.

How the data were processed

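RNA from epididymal white adipose tissue of mice was measured in 4 libraries, 2 labelled WT and 2 labelled as Nck2 knockout (KO). Per the labels' protocols, total RNA was extracted with Trizol and purified on columns, and single-read libraries were made with a TruSeq RNA kit. The standard form of that kit does not mark strand. Per the submitters' processing notes, the tools were CASAVA 1.8, TopHat2 2.0.10, HTSeq 0.5.3 and DESeq2 1.4.5 with the GRCm38 build. How strand was used in counting is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart.

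The authors deposited normalized counts, a signal per gene that is the read count divided by a size factor for the library, for 39179 genes. The authors also deposited a comparison table with log2 fold changes, p-values and adjusted p-values, and a score per gene for their test statistic. The library columns of the 2 files were identical (largest difference 0). Whole reads were recovered by dividing each column by the value of a single read, and 100% of the values came out whole within a tolerance of 0.01. The size factors were 0.9815, 1.0748, 1.0673 and 0.8962 for WT replicates 1 and 2 and KO replicates 1 and 2. Replicates differed beyond sampling noise, with a chi-square per degree of freedom of 52.3 between the WT libraries and 36.8 between the KO libraries. Totals were 31831904, 34056187, 37980391 and 33880872 reads. A count of 0 allows up to 3 reads. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

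Samples were grouped by genotype from the labels. Genes with a mean normalized count of 10 or more were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with an intensity trend, and p-values were adjusted by Benjamini-Hochberg at 0.05. The pseudocount understates the change of low genes. The prior degrees of freedom were 2.36. Gene lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Lists, tests and the rule for named genes were chosen before the data were examined. The rule takes Nck2, then the 12 greatest rises and 12 greatest falls among genes with a mean of 50 or more and both KO libraries on the same side of both WT libraries, up to 4 members of each list by smallest p, and 7 genes by name (Pparg, Cebpa, Adipoq, Lep, Fabp4, Ucp1 and Nck1). Where a symbol occurred more than once, the row with the highest mean was used for lists. Positions came from GENCODE M21 (GRCm38) for 37607 genes (96%). Genes within 20 Mb of Nck2 were compared with all others by Fisher's exact test.

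The steps were tested on simulated data in which 200 genes were changed. With variation between replicates that followed the trend over expression, limma recovered 10% of genes changed 1.5-fold, 50% changed 2-fold, 78% changed 4-fold and 98% changed 8-fold among 16537 genes, and 3.28% of its calls were false. With variation set gene by gene, it recovered 0%, 34%, 76% and 92% among 16532 genes, and 15.1% of its calls were false, so the adjusted p-values may be too small for genes that vary more than others of their level. In the second simulation 15.3% of edgeR's calls and 38.2% of DESeq2's were false. The data had far more calls than 200, with 3735 genes higher and 4074 lower. Recovery and the share of false calls depend on how many genes change, so these figures need not hold for the data. In a further simulation with 1 of 31 lists raised, camera called that list and 1 unchanged list.

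Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of 50 or more, upper-quartile and TMM scaling, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, robust moderation, the replicate number as a block, each library left out, and windows of 10 and 40 Mb. Leaving out a library leaves 1 sample in its group, which is then assumed to vary like the other group. Such a fit also has fewer residual degrees of freedom, so a lost call need not mean that the fold change moved. After the data were seen, levels were also expressed relative to the mature adipocyte genes, by subtracting each library's mean over that list. No statement rests on the p-values of that fit, because the scaling gives every gene of a library the same shift, the residuals become nearly equal and limma's prior degrees of freedom become infinite, which makes its p-values too small. The same scaling without moderation and a test of the unscaled fold changes against the list's mean were therefore added, and the counts from all 3 are given.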

Results

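Polyadenylated RNA from the epididymal white adipose tissue, the fat pad attached to the epididymis of male mice, was sequenced in 2 libraries labelled wild-type (WT) and 2 labelled as Nck2 knockout (KO), on a mixed genetic background. WT and KO stand for these labels throughout. Nck2 encodes an adaptor protein that links tyrosine-phosphorylated receptors to regulators of the actin cytoskeleton. The libraries held 31831904 reads (WT replicate 1), 34056187 (WT replicate 2), 37980391 (KO replicate 1) and 33880872 (KO replicate 2) assigned to genes. Values are normalized read counts, given as mean ± SD with n = 2 libraries per group, and fold changes are KO minus WT on the log2(normalized count + 1) scale with their standard error (SE). Adjusted p-values are Benjamini-Hochberg values from limma over 16710 genes unless another tool is named. The labels do not say that the replicates of a group came from separate animals, so the p-values measure the spread between these samples only.

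The targeted gene was examined first. Nck2 (ENSMUSG00000066877, GRCm38 chromosome 1, 43444579 to 43570515) was at 1279 and 1667 normalized counts in the WT libraries and at 1076 and 947 in the KO libraries, so both KO libraries were below both WT libraries. The log2 fold change was -0.53 (SE 0.16), and its adjusted p of 0.0509 missed the threshold of 0.05. DESeq2 on the recovered reads gave -0.55 with an adjusted p of 0.0184, and a pseudocount of 5 gave 0.0495. Over the alternatives planned before the data were examined, the adjusted p ran from 0.0184 to 0.186. Without WT replicate 2 the fold change was -0.34 (adjusted p = 0.186). The value is a total over the annotated exons of the gene, and which part of the gene was altered is not given in the sources used here, so it cannot check the genotype labels. Its paralog Nck1 (ENSMUSG00000032475) rose by 0.73 (SE 0.065, adjusted p = 0.0025), from 1174 ± 38.9 to 1946 ± 28.7. In the same comparison mature adipocyte genes had a median log2 fold change of 1.62. The WT libraries also held far more male tract and smooth muscle transcripts (below). Neither the Nck2 nor the Nck1 change can therefore be told apart from a difference in tissue content.

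**Figure D1:**
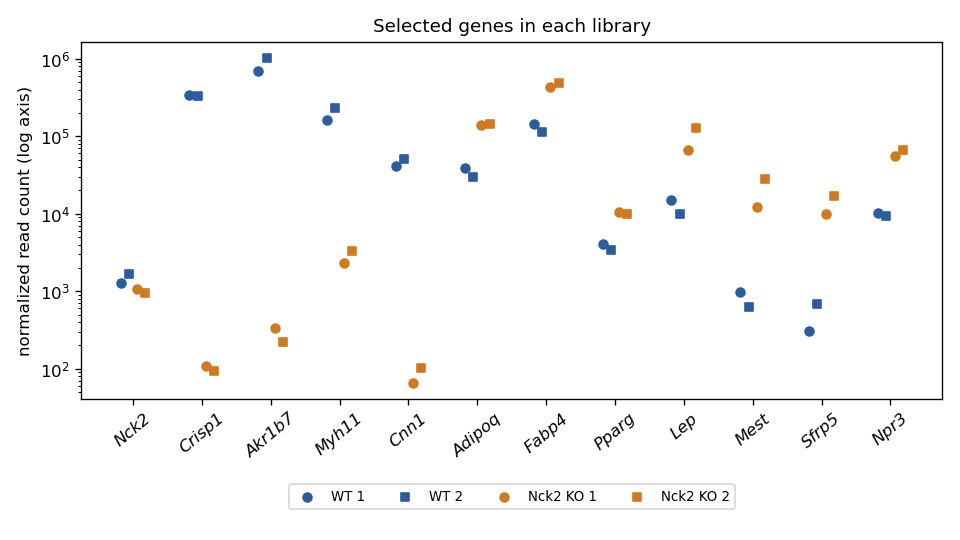
Normalized read counts (log axis) of 12 genes in each of the 4 libraries, blue for WT and orange for KO, circles for replicate 1 and squares for replicate 2. Crisp1 stands at 343811 and 334537 in the WT libraries against 108 and 94 in the KO libraries, and Adipoq at 39441 and 29702 against 140913 and 142401.

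The question the design puts is which transcripts of the fat pad differ between Nck2 genotypes. In the KO libraries 3735 genes were higher and 4074 lower, and 2 of the 12 greatest falls, Crisp1 and Adam7, were in genes of the male tract list. That count reflects which symbols the list held, and not how many of the 12 mark male tract tissue. All 12 fell by 11.26 or more, and Akr1b7, outside the list, is abundant in the vas deferens. Crisp1, which encodes a secretory protein of the epididymis, was at 339174 ± 6558 in WT and 101 ± 9.9 in KO. Akr1b7, an aldo-keto reductase abundant in the vas deferens, was at 855367 ± 226037 in WT and 279 ± 82.3 in KO. Spink8 was at 42533 ± 13.3 against 12.6 ± 2.0, Serpina1f at 72987 ± 11030 against 25.5 ± 0.3, and Cuzd1 at 33502 ± 13468 against 9.3 ± 2.6. Adam7, Pax8, Ly6f, Anxa13, Defb22 and Pcp4 had between 1 and 5 reads in both KO libraries together. For Pax8, with 1 KO read, WT exceeded KO 8470-fold, with an exact 95% interval of 1520 to 335000 that covers counting error only. Atp10b had 0 KO reads and was 2320-fold higher in WT against a floor of 3 reads over the group. The lower limit of its exact 95% interval was 1880-fold. Crisp1, Akr1b7, Serpina1f, Defb22 and Ly6f belong to families of similar genes, and their reads may be shared among copies. Adam7 had an adjusted p of 0.055 without WT replicate 2. The edgeR quasi-likelihood test on recovered reads called 3503 genes higher and 4070 lower. The counts of higher and lower genes were 1406 and 1765 without WT replicate 1, 650 and 1163 without WT replicate 2, and 2425 and 3255 without KO replicate 2. Of the calls, 47.8% were higher in KO. Expressing levels relative to the mature adipocyte genes subtracts about the same amount from every gene and moved the median of all genes to -1.5, which by itself turns most calls downward. Tested against the mean of that list, 191 genes were higher and 14545 lower (1.3% higher). Scaling each library gave 178 and 13723 (1.28% higher), and the same scaling without variance moderation gave 0 and 2.

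Of 20 tested epididymis and male tract genes, 11 fell, 0 rose and 9 did not pass, with a median log2 fold change of -8.16 and 15 lower adjusted over the list alone. Setting the 7 members without KO reads to the floor of 3 reads gave a median of -8.15. The size of that median depended on the WT libraries and on the settings. It was -6.58 without WT replicate 1 and -10.41 without WT replicate 2. With pseudocounts of 0.5 and 5 it was -8.83 and -6.24, with no filter -5.79, with edgeR -10.98 and with DESeq2 -10.77. The list took 1.26% of reads in WT replicate 1 (exact 95% interval 1.26 to 1.27) and 1.1% in WT replicate 2 (1.09 to 1.1), against 0.000395% (0.000334 to 0.000463) and 0.000578% (5e-04 to 0.000665) in the KO libraries. Most of the WT share was Crisp1, with 697008 reads over both WT libraries, in which the list held 401781 and 373452. Of 15 pericyte and smooth muscle genes, 10 fell and 1 rose (10 lower and 3 higher adjusted over the list alone), with a median of -3.81. Myh11, the smooth muscle myosin heavy chain, was at 159714 and 229497 in WT against 2282 and 3267 in KO, and Cnn1, encoding calponin, fell by 9.12 (SE 0.24, adjusted p = 0.00052). The list took 1.66% (exact 95% interval 1.65 to 1.66) and 2.24% (2.24 to 2.25) of the WT reads, against 0.115% (0.114 to 0.116) and 0.126% (0.125 to 0.128) of the KO reads. Both lists passed camera, a test against all other genes (adjusted p = 6.95e-06 and 0.0024), and neither did with an estimated correlation (adjusted p = 0.68 and adjusted p = 0.7).

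Mature adipocyte genes were higher in the KO libraries. Of 23 tested, 17 rose, 0 fell and 6 did not pass (20 rose adjusted over the list alone). The median log2 fold change was 1.62 (SD 0.65 over genes, camera adjusted p = 2.69e-06, adjusted p = 0.68 with an estimated correlation). The list did not pass the self-contained fry test (adjusted p = 0.0732). Adipoq, encoding adiponectin, rose by 2.05 (SE 0.21, adjusted p = 0.0033), Pparg, the regulator of adipocyte differentiation, by 1.46 (SE 0.10, adjusted p = 0.0016), and Lep, encoding leptin, by 2.92 (SE 0.39, adjusted p = 0.0064). Fabp4, a fatty acid carrier, rose by 1.85 (adjusted p = 0.0167) and Cebpa by 1.81 (adjusted p = 0.0167). Without WT replicate 2 the log2 fold change was 1.84 for Adipoq, 2.62 for Lep and 1.66 for Fabp4, and these did not pass. Without WT replicate 1 it was 3.23 for Lep and 2.03 for Fabp4, which did not pass. Without KO replicate 2 it was 1.77 for both Fabp4 and Cebpa, and neither passed. Without KO replicate 1 it was 1.85 for Cebpa, which did not pass. Each of these fits has fewer degrees of freedom. The adipocyte list took 3.69% (exact 95% interval 3.68 to 3.69) and 2.54% (2.53 to 2.54) of WT reads, and 7.83% (7.82 to 7.84) and 8.26% (8.26 to 8.27) of KO reads, in the same libraries in which the male tract list took 1.26% and 1.1% of WT reads.

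**Figure D2:**
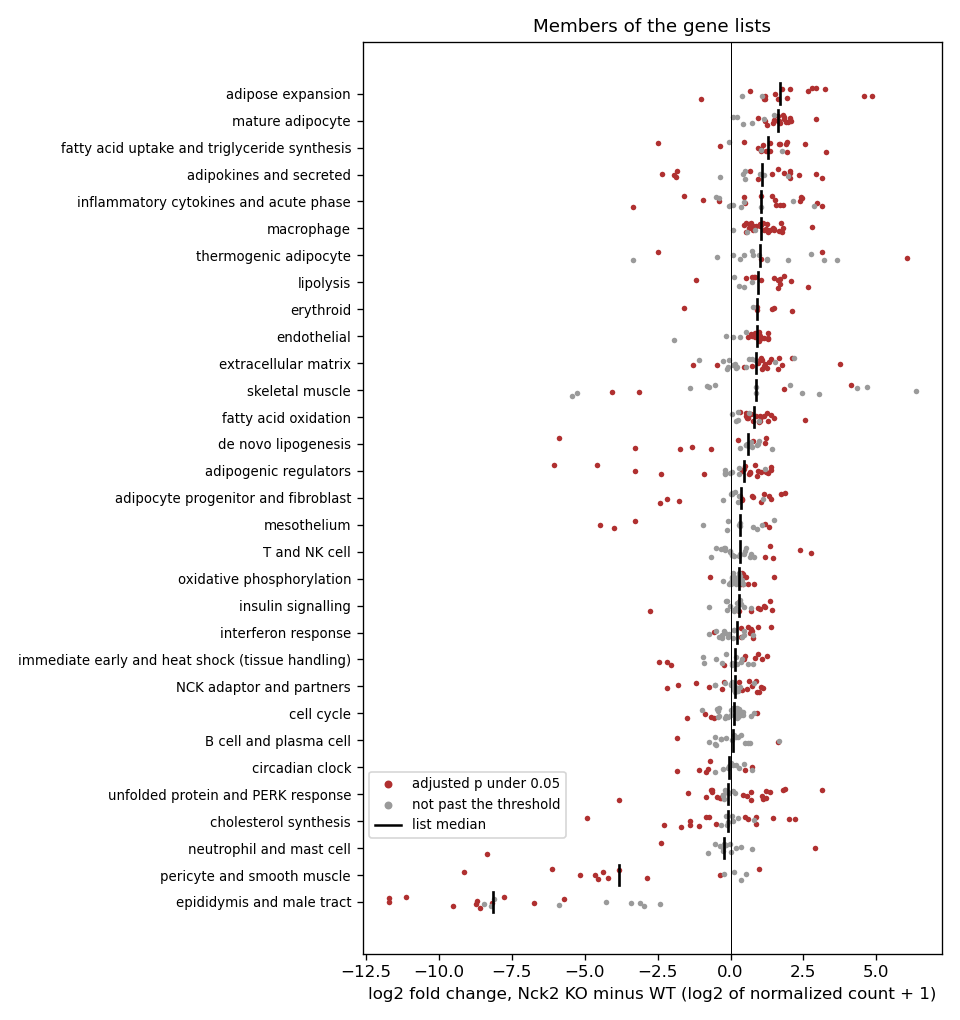
Log2 fold change (KO minus WT, horizontal axis) of each tested member of 31 gene lists (vertical axis), red where the adjusted p was under 0.05 and grey otherwise, with the list median as a black bar. The medians run from -8.16 for male tract genes to 1.7 for adipose expansion genes, with 1.62 for mature adipocyte genes.

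The other lipid lists are given beside that adipocyte median of 1.62, since male tract and smooth muscle genes were lower in KO in the same comparison. Adipose expansion genes rose in 15 of 18 and fell in 1 (16 and 1 adjusted over the list alone), with a median of 1.7, which is 0.09 above the adipocyte list. Npr3, the natriuretic peptide clearance receptor, rose by 2.67 (SE 0.14, adjusted p = 0.00089) and Peg3, an imprinted gene, by 3.25 (SE 0.24, adjusted p = 0.0017, or 0.0505 without WT replicate 2). Fatty acid uptake and triglyceride genes rose in 15 of 20 and fell in 2 (16 and 2 adjusted over the list alone, median 1.28), lipolysis genes rose in 13 of 18 and fell in 1 (13 and 1 adjusted over the list alone, median 0.95), and fatty acid oxidation genes rose in 18 of 24 (19 adjusted over the list alone, median 0.81). Relative to the adipocyte median these lists were at -0.33, -0.67 and -0.8. The uptake list shares Lpl, Cd36 and Agpat2 with the adipocyte list. The lipolysis list shares Pnpla2, Lipe, Plin1 and Adrb3 with it, and the expansion list Lep and Cav1. Their medians are therefore not independent of the adipocyte median. Oxidative phosphorylation genes rose in 14 of 41 and fell in 1 (2 and 1 adjusted over the list alone, median 0.29). Camera gave adjusted p-values of 2.59e-05, 0.00039, 0.000124, 2.24e-06 and 0.000694 for these 5 lists in that order, and with an estimated correlation the adjusted p was 0.68, 0.7, 0.68, 0.68 and 0.86. De novo lipogenesis genes did not pass (4 higher and 5 lower of 20, also 4 and 5 adjusted over the list alone, camera adjusted p = 0.545), and their median of 0.6 and mean of -0.06 differed in sign. That list passed without WT replicate 1 (median 1.17, adjusted p = 0.0383), and its median was 0.13 without WT replicate 2. The oxidative phosphorylation median was 0.18 without KO replicate 2. Fads2 and Fads1, the fatty acid desaturases, fell by 5.87 (SE 0.29, adjusted p = 0.00085) and 3.27 (SE 0.20, adjusted p = 0.0012).

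Adipogenic regulators rose in 14 of 27 and fell in 5 (17 and 6 adjusted over the list alone), with a median of 0.47, a mean of -0.13 and an upward camera test (adjusted p = 0.0395, adjusted p = 0.68 with an estimated correlation). Gata3 and Gata2, which restrain adipocyte differentiation, fell by 6.05 (SE 0.26) and 2.38 (SE 0.14), in the same comparison in which the male tract median was -8.16 and the smooth muscle median -3.81. Adipokine and secreted factor genes rose in 11 of 22 and fell in 4 (12 and 4 adjusted over the list alone, median 1.09, camera adjusted p = 0.0384, adjusted p = 0.68 with an estimated correlation). Without WT replicate 2 the camera adjusted p was 0.0567 for the regulators and 0.086 for the adipokines, and without KO replicate 2 it was 0.062 and 0.0635. With edgeR it was 0.155 and 0.158, with DESeq2 0.239 for the regulators, and with a mean of 50 or more 0.0578 for the adipokines. Thermogenic adipocyte genes did not pass (3 higher and 1 lower of 18, the same counts adjusted over the list alone, median 1.01, camera adjusted p = 0.058). The list passed without KO replicate 1 (median 1.45, adjusted p = 0.00273), with no filter (0.014), with upper-quartile scaling (0.0421) and with TMM scaling (0.0473), and its median was 0.5 without KO replicate 2. Ucp1, the uncoupling protein of brown fat, was at 21 and 6 in WT and at 228 and 2842 in KO (adjusted p = 0.0262), and its adjusted p was 0.206 without WT replicate 2 and 0.129 without WT replicate 1.

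The 12 greatest rises were in Ear11, Ucp1, Mrgprg, Slc5a7, Gabrr2, Lctl, Serpina1b, Sfrp5, Mest, Kcnj14, Duox1 and Cdsn. Sfrp5, a secreted Wnt antagonist, rose by 4.84 (SE 0.47, adjusted p = 0.0030), from 493 ± 265 to 13520 ± 4978. Mest, an imprinted gene, rose by 4.56 (SE 0.47, adjusted p = 0.0033), from 805 ± 264 to 20078 ± 10995. Lctl rose by 4.98 (SE 0.25, adjusted p = 0.00085) and Gabrr2 by 5.49 (SE 0.27, adjusted p = 0.00086). Ear11 had 1.0 ± 0.1 in WT and 239 ± 146 in KO. Ear11 and Serpina1b have close paralogs, so their reads may be shared. The log2 fold changes without KO replicate 1 and without KO replicate 2 were 5.15 and 3.97 for Mest, 7.44 and 6.12 for Ear11, and 7.87 and 4.24 for Ucp1. Ucp1 was at 6.94 without WT replicate 1 and 5.17 without WT replicate 2, against 6.05 with all libraries. These rises were measured in the same libraries as the male tract median of -8.16 and the smooth muscle median of -3.81. Without WT replicate 2 the log2 fold change was 4.22 for Mest, 4.32 for Serpina1b, 6.75 for Ear11 and 5.24 for Mrgprg. It was 6 for Slc5a7, 3.94 for Kcnj14, 4.94 for Cdsn and 5.17 for Ucp1. These genes did not pass in that fit, which has fewer degrees of freedom. Without WT replicate 1 the log2 fold change was 4.9 for Mest, 5.21 for Slc5a7, 4.65 for Kcnj14, 3.54 for Cdsn and 6.94 for Ucp1. These did not pass there either.

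Macrophage genes rose in 28 of 31 and fell in 0 (29 rose adjusted over the list alone), with a median of 1.04 and a camera adjusted p of 1.32e-10 (adjusted p = 0.68 with an estimated correlation). Ctss, a lysosomal protease, rose by 1.29 (SE 0.063) and Tyrobp, a myeloid signalling adaptor, by 1.25 (SE 0.070). Inflammatory and acute phase genes rose in 13 of 27 and fell in 4 (13 and 4 adjusted over the list alone, median 1.05, or 0.58 without WT replicate 2). Ccl11 rose by 2.45 (SE 0.15) and Lcn2 fell by 3.35 (SE 0.16). Endothelial genes rose in 15 of 20 (16 higher and 1 lower adjusted over the list alone, median 0.91), with Kdr, a receptor for vascular endothelial growth factor, up by 1.30 (SE 0.13). Extracellular matrix genes rose in 17 of 34 and fell in 2 (18 and 2 adjusted over the list alone, median 0.89), with Col5a3 up by 2.09 (SE 0.22). Progenitor and fibroblast genes rose in 11 of 22 and fell in 3 (11 and 3 adjusted over the list alone, median 0.36), and insulin signalling genes rose in 9 of 24 and fell in 1 (9 and 1 adjusted over the list alone, median 0.29). Camera gave adjusted p-values of 0.0148, 9.36e-05, 0.000235, 0.0175 and 0.0146 for the inflammatory, endothelial, matrix, progenitor and insulin lists, and with an estimated correlation the adjusted p was 0.68 for each of the 5. The progenitor list did not pass without WT replicate 2 (adjusted p = 0.0512) or without KO replicate 1 (adjusted p = 0.0528), nor did the insulin list without WT replicate 2 (adjusted p = 0.0573). With edgeR the adjusted p was 0.0801 for the progenitor list and 0.0893 for the insulin list, and with DESeq2 it was 0.0702 for the insulin list. Without WT replicate 2 the adjusted p was 0.0529 for Kdr and 0.0524 for Col5a3. In the same comparison the smooth muscle median was -3.81 and the male tract median -8.16, and each of these medians lay below the adipocyte median of 1.62.

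Of the 31 lists, 16 passed camera (14 upward and 2 downward). With an estimated correlation 0 passed at an adjusted p and 2 at an unadjusted p under 0.05. The self-contained fry test called 5, the male tract, macrophage, lipolysis, smooth muscle and adipose expansion lists. Several upward lists share members, as with Adipoq, Lep, Retn and Cfd in the adipocyte and adipokine lists. The upward lists are therefore not separate findings. Besides the de novo lipogenesis and thermogenic lists, the lists that did not pass, with genes higher and lower of those tested, were interferon response (9 and 1 of 26), T and NK cell (5 and 0 of 24), B and plasma cell (1 and 1 of 18), neutrophil and mast cell (1 and 2 of 15), mesothelium (2 and 3 of 15), skeletal muscle (2 and 2 of 18), erythroid (5 and 1 of 7), unfolded protein and PERK response (12 and 10 of 31), cholesterol synthesis (7 and 9 of 24), cell cycle (1 and 4 of 32), NCK adaptors and partners (11 and 6 of 35), tissue handling (6 and 4 of 24) and circadian clock (2 and 5 of 17). Adjusted over the list alone, the numbers higher and lower were 9 and 1, 5 and 0, 0 and 1, 1 and 2, 1 and 1, 1 and 2, 6 and 1, 12 and 10, 7 and 9, 0 and 0, 11 and 7, 6 and 3, and 2 and 4 in that order. Among all lists that did not pass, the medians ran from -0.21 for neutrophil and mast cell genes (0.21 without WT replicate 2) to 1.01 for thermogenic genes, with 0.93 for erythroid genes. Without KO replicate 2 the interferon (adjusted p = 0.00227), T and NK cell (0.0485) and mesothelium lists (median 1.39, 0.0279) passed, and without KO replicate 1 the erythroid (0.035) and NCK partner lists (0.0315) did. The mesothelium median was 0.33 with all libraries, -0.05 without WT replicate 1 and -0.81 without KO replicate 1 (adjusted p = 0.052), so its sign depended on the libraries. The skeletal muscle median was 2.61 without KO replicate 1 (adjusted p = 0.0152) and -2.45 without KO replicate 2 (adjusted p = 0.00955). With no filter the interferon, T and NK cell, erythroid and NCK partner lists passed. Within the unfolded protein list Trib3, a target of the PERK branch, rose by 1.86 (SE 0.13) and Ern1, which encodes the sensor IRE1, fell by 1.44 (SE 0.080). Among NCK partners Pak1 fell by 2.18 (SE 0.18) and Efnb1 rose by 1.13 (SE 0.078), beside the smooth muscle median of -3.81 and the male tract median of -8.16.

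Genes around Nck2 were compared with the rest of the genome, since sequence that flanks a targeted gene can differ in origin on a mixed background. Within 20 Mb of Nck2, 91 of 184 tested genes (49.5%) passed the threshold, against 7672 of 16354 elsewhere (46.9%), with Nck2 left out. The odds ratio was 1.11 (95% interval 0.819 to 1.5, two-sided Fisher's exact test p = 0.504), so no difference was detectable. With 46.9% of genes elsewhere passing, a few altered genes near Nck2 would barely move the share. The test therefore cannot exclude an effect of flanking sequence.

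The authors' deposited table lists 3593 genes higher and 4142 lower at an adjusted p under 0.05, and it gives Nck2 a log2 fold change of -0.54 with an adjusted p of 0.0208. Against the authors' deposited table, 7101 genes were called in both with the same sign and 0 with opposite signs, and Spearman's rho across 16710 genes was 0.997. Both analyses used the same 4 libraries, and genes are not independent replicates.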

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

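The adipocyte-relative settings were chosen after the data were seen, and the rest before. Nck2 stayed lower in KO in every setting run, but its adjusted p of 0.0509 sits at the threshold. It passed with a pseudocount of 5 (-0.53, adjusted p = 0.0495) and with DESeq2 (-0.55, adjusted p = 0.0184), and ran from -0.72 to -0.34 with a library left out. Relative to adipocyte genes it was -1.99, a shift made for every gene, with an adjusted p of 3.17e-07 in the fit with infinite prior degrees of freedom, 0.0817 without moderation and 0.000296 against the list mean, so that call rests on the variance model. For the same 3 settings the genes higher and lower were 178 and 13723, 0 and 2, and 191 and 14545, and the median of all genes shifted to -1.5. With a library left out, genes higher ran from 650 to 2849, genes lower from 1163 to 3477 and the overlap with the authors' deposited table from 1773 to 5917, and the cause was not tested. Of 145 named genes, 47 lost their call without WT replicate 1, 71 without WT replicate 2, 3 without KO replicate 1 and 7 without KO replicate 2. The lists passing camera ran from 12 to 19 with a library left out and fell to 0 with an estimated correlation. The median of skeletal muscle genes ran from -2.45 without KO replicate 2 to 2.61 without KO replicate 1, and the cause was not tested. The odds ratio of genes near Nck2 changed side of 1 without reaching the threshold, from 0.71 to 1.03 with a library left out and at 0.993 with the replicate block, and the cause was not tested.

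Same-numbered replicates share only a number, since the labels do not say that it marks a litter or day. The correlation of their deviations was -0.009 across genes, and the replicate block gave 2737 genes higher and 3339 lower. Of the named genes called without the block, 5 did not pass under it, among them Fabp4 (adjusted p = 0.0903) and Ucp1 (0.0517), and the thermogenic and erythroid lists passed (0.0424 and 0.0356). Depth limits genes with few KO reads, for which folds carry wide counting intervals.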

Other observations

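All tests in this part except that of the imprinted genes were chosen after the results were seen. Libraries of a group differed in transcripts of further tissues, in genes chosen after their values were seen. Svs2, Svs4 and Svs5, which encode seminal vesicle secretions, were at 12085, 11735 and 11146 in WT replicate 1 and at 63.3, 6.5 and 0.9 in WT replicate 2. Myh4 and Atp2a1, skeletal muscle genes, were at 1685 and 1271 in KO replicate 2, at 15.0 and 17.8 in KO replicate 1, at 3.1 and 9.2 in WT replicate 1 and at 0.0 and 4.7 in WT replicate 2. Other genes of that list went the other way, with Acta1 at 9138 and 13526 in WT against 811 and 1955 in KO. Upk3b, a mesothelial gene, was at 8866 in KO replicate 1, 1643 in KO replicate 2, and 2271 and 4040 in the WT libraries.

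The higher mature adipocyte genes in KO were weighed first. Distortion of library totals by abundant WT transcripts was examined as a cause. The 1328 genes over 3 log2 lower in KO took 9.99% and 12.7% of WT reads, and on library totals without them the adipocyte median was 1.25, against 1.42 on all reads and an SD of 0.65 over genes. These genes were chosen from the same fold changes, and their share of reads alone sets the shift, which is equal for every gene. The check shows only that, on library totals, leaving these genes out did not remove the adipocyte rise. It does not cover the deposited size factors, which gave 1.62, so it decides nothing for them. A candidate explanation is that male tract and smooth muscle RNA in the WT libraries diluted adipocyte RNA. In WT replicate 2 against replicate 1 the adipocyte median was -0.50, lower in 23 of 23 genes. The smooth muscle median was 0.24 but the male tract median was -0.81, so the lists that should mark the diluting tissue moved apart and the test decides nothing. The male tract list includes the Svs genes, which were far higher in WT replicate 1. Other members were also higher there, such as Adam7 (9918 against 6092) and Rnase9 (4500 against 2324). Defb2 (207 against 232) went the other way. The 1328 genes above took more reads in WT replicate 2 (12.7% against 9.99%), the direction dilution would give, but they were chosen from these data. Tissue content and genotype are confounded, so dilution, a difference in dissection and an effect of Nck2 cannot be told apart here.

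Genes such as Mest and Sfrp5 had greater folds than the adipocyte list, and 96 genes lay above its highest member, Lep at 2.92, with both KO libraries above both WT libraries. Dilution alone should raise adipocyte transcripts by a single factor. A one-sided limma test against the list mean of 1.45, adjusted by Benjamini-Hochberg, called 0 genes (smallest adjusted p 0.12), with 281 at an unadjusted p under 0.05. The two-sided form of the same test called 191 genes higher, at a cutoff that its 14545 lower calls relaxed, and the fit scaled per library called 178, with infinite prior degrees of freedom. These forms differ, so whether these genes rose beyond dilution cannot be told apart from it with 2 libraries per group.

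A further hypothesis was that imprinted genes as a class were higher, prompted by Mest, Peg3, Nnat and Grb10. Of 29 other imprinted genes, written down before their values were seen, 23 were tested, 8 rose and 2 fell. Their median was 0.24, below the adipocyte median of 1.62. Zim1 (3.43) and Copg2 (-0.165) lie beside Peg3 and Mest, so they are not independent of the genes that prompted the test. Tissue content differs between the groups, so the shift cannot be assigned to imprinting. Camera gave an upward p of 0.021 with the preset correlation and p = 0.13 with an estimated correlation. Peg10 rose by 2.66 and Slc38a4 fell by 6.55 (SE 1.23). Slc38a4 was at 1.9 and 33.5 in the KO libraries, so the size of its fall is uncertain. The class may be raised only in part, and the call depends on the assumed correlation.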
